A study of Drosophila melanogaster with 2 samples.

How the data were processed

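Total RNA from adult heads was extracted with Trizol and made into libraries with standard Illumina protocols, per the labels' protocols, with 1 library from flies on the control diet and 1 from flies on the control diet with sucralose. The authors deposited 1 table per library, listing each gene with at least 1 read by its FlyBase gene number. Per the file headers, the count column holds the number of unique reads per gene, as raw whole numbers whose sum equals the total in the header (10.3 M and 10.4 M reads). The deposited RPKM values are reads scaled by gene length and by that total, and recomputing them from the deposited counts and lengths gave the same values. The deposited coverage is the percent of each gene model's bases that reads cover, and the deposited length is that of the gene model. The aligner, genome build and annotation release are not given in the sources used here, nor is strandedness. Reads of near-identical copies may be lost because unique reads were counted, and reads of overlapping genes on both strands may be mixed. Of the 146 named genes, 14 share at least 20% of their exon bases with another gene in the BDGP6.54 annotation, which was used for that check and for no coordinates.

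Gene symbols were matched through a table of gene identifiers. Of 12083 genes listed in either library, 496 had no match (6.07% and 6.12% of reads) and kept their identifiers. Counts were scaled with the trimmed mean of M-values (TMM) of edgeR 4.0.16 in R 4.3.3, with factors of 0.998 and 1.002, and differences are log2 of (CPM + 0.5), sucralose minus control. Genes with at least 50 reads summed over both libraries were counted, and a list was ranked when at least 4 members passed that floor. Folds are ratios of scaled counts, with conditional exact binomial (Clopper-Pearson) 95% intervals. A count of 0 is treated as at most 3 counts (0.293 CPM in the control and 0.287 CPM in the sucralose library). PCR reads without molecular identifiers are not independent molecules, so the intervals cover counting error only. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1 did the rest.

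The 35 gene lists, the filters, the alternatives and the naming rule were fixed before the data were examined. The rule takes the 12 highest and 12 lowest genes with at least 200 summed reads, up to 4 members of each list by size of difference (1 of them the most abundant), and a fixed set of peptide, insulin, taste and amine genes whatever their values. Each list's median was ranked among 10000 seeded random lists of the same size, drawn from 10 classes of mean expression, and called higher or lower beyond percentile 97.5 or 2.5. Counting noise was simulated 100 times with both libraries given the same underlying levels.

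On simulated data for this comparison, run on 12083 genes, 99 of 100 doubled genes and 95 of 100 halved genes were found beyond 1.5-fold, with 40 of 8391 unchanged genes also beyond it. Intervals held the true fold for 190 of 200 changed genes. All 20 lists shifted 1.25-fold were called, as were 10 of 200 lists not shifted. The simulation held counting noise alone and drew its lists from genes at random. The rate for lists not shifted thus followed from the percentile cut-offs. None of these rates is an error rate for the real genes and lists.

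Alternatives were other scalings (total counts, median centring, upper quartile), pseudocounts of 0.1 and 5, no filter or a floor of 200 reads, list means, lists without their most extreme member, and random lists not matched on expression. Chosen after seeing the data were scaling without the 20 most abundant genes, counting without the gut, carbohydrase, muscle and fat body lists, random lists matched on length, and lists without Akh. Another 5 lists, named in the closing section with their results, were also added: midgut genes outside the proteases, mitochondrially encoded mRNAs, tyrosine breakdown, other glial genes and other photoreceptor genes.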

Results

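RNA from whole heads of adult Drosophila melanogaster of the white-eyed laboratory strain w1118 was sequenced after 6 days on either a standard diet or the same diet with sucralose, a chlorinated sugar derivative that tastes sweet and carries almost no usable energy. Flies were 4 to 7 days old when the diets began and 10 to 14 days old at collection. Each diet is represented by 1 library, so there is no spread between replicates, no test of the diets can be made and no p-value is given. The control library held 10.3 M uniquely assigned reads over 11521 genes, and the sucralose library held 10.4 M reads over 11588 genes. Every fold below is the sucralose library over the control library, or its inverse where a gene is called lower. Its 95% interval is an exact binomial (Clopper-Pearson) interval that covers counting error only and compares these 2 libraries, not the diets. The study asked, as its title states, whether sucralose raises feeding through neuropeptide Y signalling and a fasting-like state of neurons.

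Among genes with at least 200 reads summed over both libraries, the highest fold belonged to Cyp4g1, an oenocyte P450 enzyme that makes cuticular hydrocarbons, with 20 reads in the control and 365 in the sucralose library (17.9-fold higher, 11.4 to 29.7). Dr, a homeobox transcription factor, was 7.19-fold higher (5.26 to 10.1), and Achl was 4.34-fold higher (3.34 to 5.70). Hpd, which encodes the dioxygenase of tyrosine breakdown, was 3.97-fold higher (3.69 to 4.28). The transcription factor gene sug was 2.74-fold higher (2.33 to 3.25), and Pepck1, the committed enzyme of gluconeogenesis, was 2.63-fold higher (2.55 to 2.71). The other 6 of the 12 highest genes, the cuticle protein gene Cpr72Ec together with CG13116, CG14636, CG13315, CG12256 and CG12116, lay between 2.20-fold and 2.43-fold higher. All exon bases of Pepck1 are shared with CG45087 and 85.1% of those of CG12256 with an antisense gene, so their reads are not certain to be their own.

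The 12 lowest genes were mostly digestive enzymes. CG12374, a carboxypeptidase gene, had 1208 reads in the control library and 3 in the sucralose library (410.4-fold lower, 140.1 to 1993), and CG6295, a lipase gene, had 340 reads and 1 read. The serine protease genes Jon65Aiii, Jon65Aiv, alphaTry and Jon74E were 37.1-fold, 35.1-fold, 46.2-fold and 23.6-fold lower. CG16826 was 51.8-fold lower (24.9 to 129.9). The maltase gene Mal-A6 was 5.49-fold lower (3.92 to 7.87) and the amylase gene Amy-p was 5.13-fold lower (3.83 to 6.99). Also among the 12 were the odorant-binding protein gene Obp56h (7.63-fold lower), the calcium-binding protein gene Scp1 (6.71-fold) and the larval storage protein gene Lsp2 (5.64-fold). An antisense gene shares 84.6% of the exon bases of Lsp2.

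Of 8889 genes with at least 50 summed reads, 174 were at least 1.5-fold higher in the sucralose library and 366 at least 1.5-fold lower. At the 2-fold mark, 30 were higher and 122 lower. Simulated counting noise alone gave means of 23.0 and 22.1 genes at 1.5-fold and 0.47 in each direction at 2-fold. The remaining 8349 genes (93.9%) lay within 1.5-fold, and Pearson's r of log2 CPM was 0.981 across genes, which are not independent replicates. The counts moved by over 1.5 times with the pseudocount and with the filter: a pseudocount of 5 CPM gave 61 higher and 206 lower at 1.5-fold, and no filter gave 459 and 695.

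**Figure D1:**
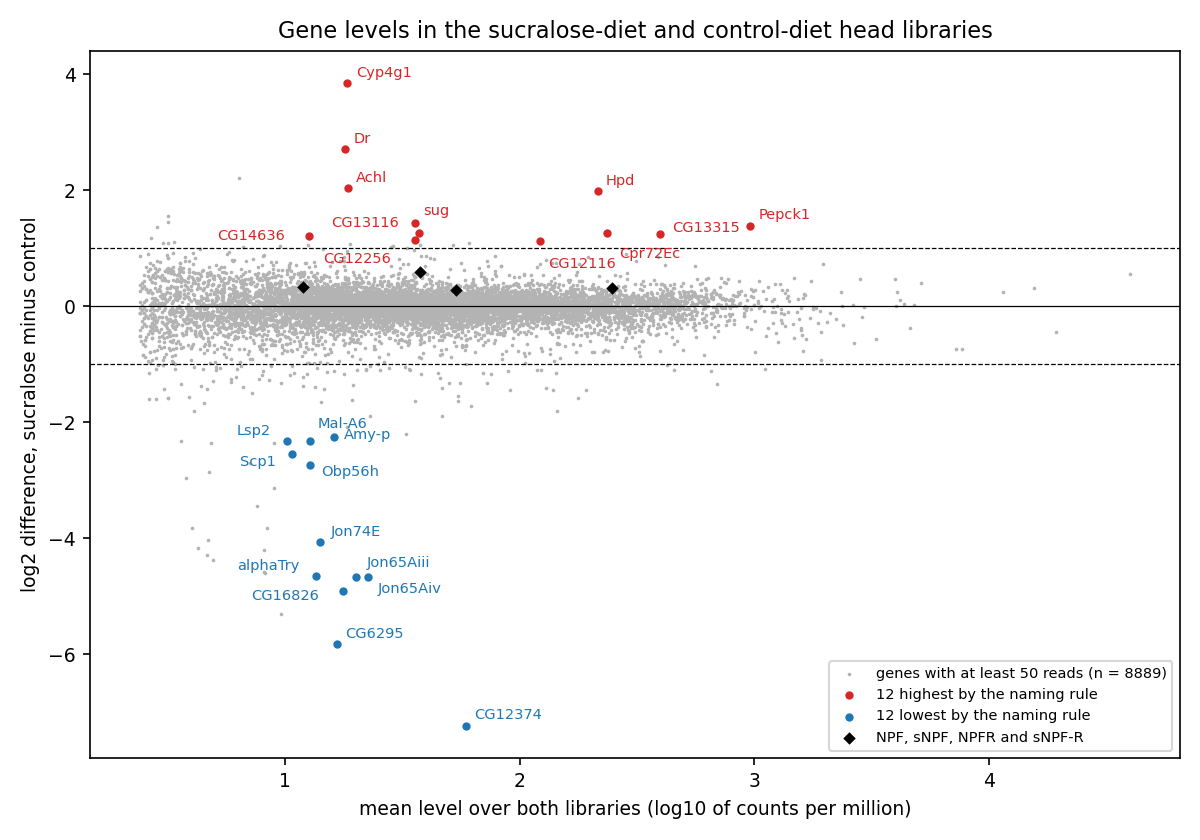
Log2 difference (sucralose minus control) against the mean level of each gene over both libraries (log10 of CPM, the scaled read count), 1 point per gene for 8889 genes and 1 library per diet, with dashed lines at 2-fold. Digestive enzyme genes such as CG12374 lie lowest (log2 -7.23) and Cyp4g1 highest (3.85), while the 4 NPY-like genes (black diamonds) lie between 0.28 and 0.59.

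The 4 genes of the fly's neuropeptide Y-like systems, which the study's title puts at the centre, were all higher in the sucralose library, 1 of them by at least 1.5-fold. NPF, the long peptide that promotes feeding, had 305 reads in the control and 471 in the sucralose library (1.51-fold higher, 1.31 to 1.76). The short peptide gene sNPF was 1.24-fold higher (1.17 to 1.31) and its receptor gene sNPF-R 1.22-fold higher (1.08 to 1.38). The NPF receptor gene NPFR, with 107 and 139 reads, was 1.27-fold higher with an interval that includes no difference (0.983 to 1.66). The median log2 difference of the list was 0.32, above 9963 of 10000 random lists of the same size and expression. Such a rank describes these libraries and is not a p-value. Markers of other tissues and cell types differed in the same library, with list medians of -4.29 for gut proteases and lysozymes, -0.34 for muscle, -0.59 for glia and 0.24 for photoreceptors.

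Other neuropeptide and peptide hormone genes were mostly slightly higher. Of 25 over the floor, 20 were above 0, 1 was at least 1.5-fold higher, 3 at least 1.5-fold lower and 21 between. The median was 0.27, above all 10000 random lists, but the mean of 0.06, at percentile 92.5, ends that call because of a few much lower members, and the reads of all 29 listed genes summed to a fold of 0.942 (0.924 to 0.961). Akh, the adipokinetic hormone made by the corpora cardiaca, had 89 reads in the control and 8 in the sucralose library (11.3-fold lower, 5.51 to 27.1). Nplp3, a neuropeptide-like precursor, was 2.14-fold lower (2.05 to 2.23), and SIFa was 1.65-fold lower (1.19 to 2.31), with 21.1% of its exon bases shared with Start1. CNMa was 1.62-fold higher (0.975 to 2.75). Mip, Dh44 and Hug, picked outside the naming rule after their values were seen, were 1.47-fold, 1.46-fold and 1.45-fold higher, close to NPF (1.51-fold). Gut protease and lysozyme genes, expressed outside the brain, were lower in the same library as Akh (list median -4.29), as were muscle markers (-0.34).

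**Figure D2:**
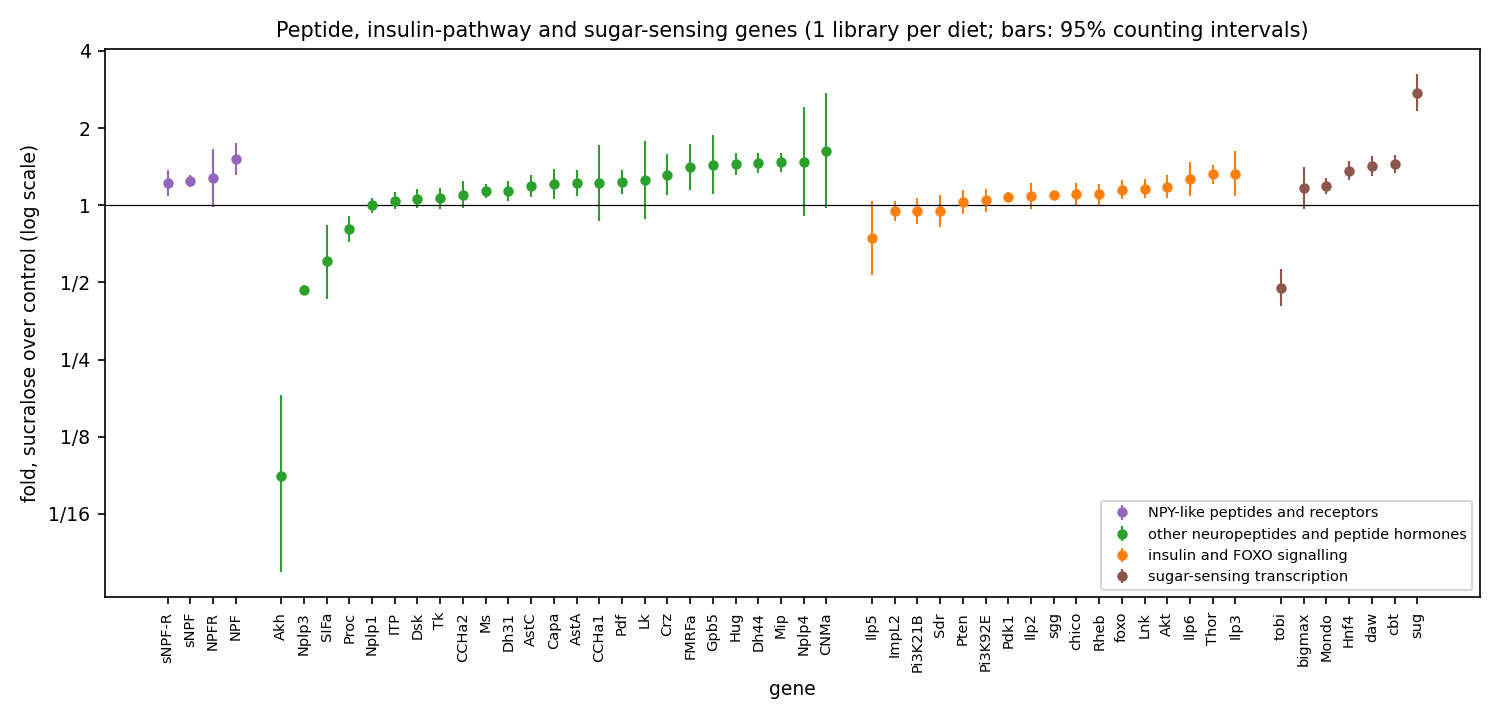
Fold, sucralose over control (log axis), of neuropeptide, insulin-pathway and sugar-sensing genes over the floor, 1 point per gene, with bars for 95% counting intervals and 1 library per diet. The 4 NPY-like genes lie between 1.22 and 1.51, Akh at 0.0882 and sug at 2.74.

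Genes of insulin and FOXO signalling were slightly higher as a list. None of the 17 matched members over the floor reached 1.5-fold either way, while 3 of the 24 listed genes had no match in the files. Thor, the 4E-BP translation inhibitor and a FOXO target, was 1.32-fold higher (1.21 to 1.43). The insulin-like peptide gene Ilp3 was 1.33-fold higher (1.09 to 1.62), Ilp2 was 1.08-fold higher (0.964 to 1.22), and Ilp5 had 87 and 66 reads (fold 0.744, 0.532 to 1.04). The list median was 0.13, above 9881 of 10000 random lists. No identifier in the files could be matched to the insulin receptor gene InR, so no value is given for it. It may be among the 496 identifiers with no matched symbol. The 13 AMPK and energy-sensing genes all lay within 1.5-fold, with a median of 0.06 that ranked above 8525 of 10000 random lists and a mean of 0.15 that ranked at percentile 99.4. AMPKalpha, the catalytic subunit, was 1.03-fold (0.965 to 1.09), and the starvation-response factor genes REPTOR and REPTOR-BP were 1.41-fold (1.31 to 1.52) and 1.36-fold (1.19 to 1.55) higher.

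Of 15 starvation-induced genes over the floor, 2 were at least 1.5-fold higher, 1 at least 1.5-fold lower and 12 between. The higher members were Pepck1 and Cyp4g1, the latter better known for cuticular hydrocarbon synthesis, and the lower one was Akh. The list median was 0.18, above 9975 of 10000 random lists, and 0.19 without Akh. Sugar-sensing transcription genes had a median of 0.45, above all 10000 random lists, with 6 of 7 above 0. Besides sug, cbt was 1.45-fold higher (1.34 to 1.57) and Mondo, the partner of bigmax in glucose sensing, was 1.19-fold higher (1.10 to 1.28). The glucosidase gene tobi was 2.09-fold lower (1.78 to 2.47). It also belongs to the digestive carbohydrase list, where all 8 members over the floor were below 0, 6 of them by at least 1.5-fold. Among 17 genes of lipid synthesis, storage and lipolysis, 1 was at least 1.5-fold higher (FASN2, 24 and 42 reads), 1 lower (CG6295) and 15 between. That list's median was 0.08 and its mean -0.26, which differ in sign through CG6295, and the mean ranked at percentile 1.41, which makes the list lower. The perilipin gene Lsd-1 was 1.37-fold lower (1.27 to 1.47), and the fatty acid desaturase gene Desat1 was 0.969-fold (0.950 to 0.989).

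Receptors for sugars were too rare in whole heads to compare. The 7 sweet taste receptor genes listed summed to 58 control and 52 sucralose reads (fold 0.880, 0.593 to 1.30), with 10 and 12 for Gr5a (74.4% of exon bases shared with an antisense gene), 4 and 2 for Gr43a, 8 and 3 for Gr64a, and 20 and 12 for Gr64f. The 15 bitter receptor genes summed to 201 and 177 reads (0.864, 0.702 to 1.06). Among them Gr39a was 1.93-fold higher (1.21 to 3.13), Gr28b had 28 and 29 reads, and Gr10a was 1.95-fold lower (1.14 to 3.42), although all its exon bases are shared with Or10a. Odorant-binding protein genes were lower, 11 of 25 by at least 1.5-fold and 1 higher by as much, with a median of -0.55 below all 10000 random lists. Obp99b was 2.96-fold lower (2.59 to 3.40) and Obp56e 2.23-fold lower (2.0 to 2.5, 84.4% of exon bases shared with an antisense gene), while the most abundant member, Obp19d, was 1.20-fold lower (1.18 to 1.22).

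Amine, cAMP, clock and activity-regulated genes showed no shift as lists, though single members differed. Among 16 dopamine and octopamine genes, the octopamine receptor gene Octbeta2R was 1.73-fold higher (1.30 to 2.30) and Pu, which acts in making the tetrahydrobiopterin cofactor, was 1.71-fold lower (1.61 to 1.81), with 14 between and a median of -0.02. The dopamine-synthesis gene ple was 0.963-fold (0.870 to 1.07) and the tyramine-synthesis gene Tdc2 was 1.05-fold (0.832 to 1.32). None of 10 cAMP pathway genes reached 1.5-fold, with a median of -0.04 and a mean of 0.02, and CrebA was 1.42-fold higher (1.23 to 1.64). Of 12 clock genes, Clk was 1.80-fold higher (1.56 to 2.07), vri 1.64-fold higher (1.57 to 1.71) and tim 1.79-fold lower (1.73 to 1.86), with a list median of 0.00. The labels give no time of day for either collection, and these genes cycle daily. Hr38, an activity-induced nuclear receptor, was 2.37-fold lower (2.06 to 2.74), while the other 6 activity-regulated genes lay within 1.5-fold. That list's median was 0.09 and its mean -0.07.

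Energy metabolism genes were lower together by small amounts. Of 31 nuclear oxidative phosphorylation genes, 30 were below 0 and none reached 1.5-fold, and the median of -0.29 lay below all 10000 random lists. The ATP/ADP carrier gene sesB was 1.35-fold lower (1.33 to 1.38) and the ATP synthase gene ATPsyngamma 1.34-fold lower (1.27 to 1.41). Glycolysis genes had a median of -0.28, with Gapdh1 1.44-fold lower (1.39 to 1.5) and the aldolase gene Ald1 1.30-fold lower (1.27 to 1.33). Tricarboxylic acid cycle genes had a median of -0.23, with SdhC 1.30-fold lower (1.20 to 1.41). Muscle markers were lower in the same library (median -0.34). Genes of cytosolic ribosomal proteins were slightly higher, 75 of 79 above 0 with a median of 0.19, above all 10000 random lists, and RpLP1 was 1.39-fold higher (1.35 to 1.44). Mitochondrial ribosomal protein genes had a median of -0.09, with 2 of 70 at least 1.5-fold lower, and ranked at percentile 5.74, no longer apart, when random lists were also matched on gene length.

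Genes of gut, muscle and fat body were mostly lower. All 11 members of the gut protease and lysozyme list over the floor, 10 proteases and the lysozyme gene LysC, were at least 1.5-fold lower. The list median was -4.29, and -4.07 on the same scale with the 3 members at 0 sucralose reads set at 3 counts. The 26 gut protease and lysozyme genes listed summed to 2411 control reads (0.0235% of the library) and 97 sucralose reads (0.00093%). Jon99Cii had 197 control reads and 0 sucralose reads, at least 66.9-fold lower against a limit of 3 counts in the sucralose library, and the lower limit of its exact interval, which also counts the error of the control reads, was 53.9-fold. Of 8 digestive carbohydrase genes, 6 were at least 1.5-fold lower (median -1.19), among them Mal-A1 (4.49-fold, 3.45 to 5.90). The Jonah proteases and the amylase pair include near-identical copies, so reads may be divided unevenly among them. None of 16 muscle markers was above 0 and 6 were at least 1.5-fold lower, with a median of -0.34. The flight muscle actin gene Act88F was 3.09-fold lower (2.11 to 4.60), Act79B 2.24-fold lower (1.95 to 2.58), fln 1.77-fold lower (1.27 to 2.47, 61.6% of exon bases shared with an antisense gene) and the myosin heavy chain gene Mhc 1.47-fold lower (1.44 to 1.51). Of 11 fat body markers, 5 were at least 1.5-fold lower and 2 higher (median -0.55), while apolpp, the main lipoprotein gene, was 1.02-fold (1.0 to 1.03).

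Sex-biased head genes gave no single direction. The yolk protein genes Yp1 (5.54-fold, 3.43 to 9.42) and Yp3 (1.83-fold, 1.65 to 2.03) were higher in the sucralose library, and fit was 6.74-fold lower (3.74 to 13.2). Yp2, under the floor with 9 control and 31 sucralose reads, was 3.38-fold higher (1.57 to 8.07). The 4 genes summed to 684 control and 1219 sucralose reads (1.75-fold higher, 1.59 to 1.92), mostly reads of Yp3. An antisense gene shares 54.3% of the exon bases of Yp1. The labels give no sex, and none of the 3 male-specific genes of the list matched an identifier in the files.

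Photoreceptor genes were mostly higher, and 6 of 11 glial genes were lower by at least 1.5-fold. Of 19 photoreceptor and phototransduction genes, 17 were above 0 and 2 reached 1.5-fold, with a median of 0.24, above all 10000 random lists, whereas 12 other photoreceptor genes, listed later, had a median of 0.05 within the range of random lists. The major rhodopsin gene ninaE, the most abundant gene, took 3.22% of control and 4.78% of sucralose reads (1.48-fold higher, 1.47 to 1.48). Rh4 was 1.66-fold (1.62 to 1.69), Rh3 1.41-fold (1.38 to 1.44) and the rhodopsin chaperone gene ninaA 1.51-fold higher (1.42 to 1.62), the last sharing all its exon bases with CG15824 on the opposite strand. Of 11 glial markers, 6 were at least 1.5-fold lower, with a median of -0.59 below all 10000 random lists. The GABA transporter gene Gat was 2.74-fold lower (2.52 to 2.98), the astrocyte gene alrm 2.74-fold (2.48 to 3.04), the gap junction gene Inx2 1.87-fold (1.73 to 2.01) and the glutamine synthetase gene Gs2 1.53-fold (1.5 to 1.57). The other 5, singled out after their values were seen, differed little: the pan-glial transcription factor gene repo was 0.956-fold (0.854 to 1.07), moody 0.912-fold, CG6126 0.984-fold, loco 1.02-fold and wrapper 1.08-fold. Neuronal markers had a median of -0.17 with none of 14 beyond 1.5-fold, a call lost without the most extreme member (-0.14). The sodium pump subunit gene nrv3 was 1.41-fold lower (1.38 to 1.44) while nSyb was 1.15-fold higher (1.12 to 1.17). Hemocyte markers had a median of -0.08, within the range of random lists.

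Immune and stress genes were mixed. Of 18 antimicrobial and immune effector genes, 6 were at least 1.5-fold lower and none as much higher, with a median of -0.35 below all 10000 random lists. DptA was 4.33-fold lower (2.49 to 8.0), DptB 2.65-fold (1.93 to 3.69) and AttB 2.33-fold (1.47 to 3.77), whereas the most abundant member, BomS2, was 1.15-fold higher (1.09 to 1.20), and the reads of the list summed to a fold of 1.09 (1.06 to 1.11). Heat-shock and chaperone genes had a median of -0.35 (mean -0.26, percentile 3.51, which ends the call), with Hsp67Bc 2.27-fold lower (1.55 to 3.38), Hsp83 1.73-fold lower (1.69 to 1.78), DnaJ-1 1.67-fold lower (1.54 to 1.80) and Hsp26 1.55-fold higher (1.14 to 2.13). The 6 Turandot stress genes summed to 376 and 360 reads. Detoxification genes had a median of -0.09, at percentile 2.43 of random lists and at 23.2 when these were also matched on length, with Cyp4p1 1.63-fold higher (1.47 to 1.80), Ugt35B1 1.61-fold lower (1.5 to 1.73) and GstE2 1.57-fold lower (1.33 to 1.85). Proteasome genes had a median of -0.04 and autophagy genes 0.02, and both lay within the range of random lists.

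Of 35 lists, 30 had enough members to rank, and 7 were higher, 14 lower and 9 within the central 95% of random lists. Among 30 lists of randomly drawn genes, 1.5 would fall outside. The lists here hold genes of the same tissue or pathway, and some share members such as Thor and tobi. For these lists 1.5 is therefore not the number due to chance.

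**Figure D3:**
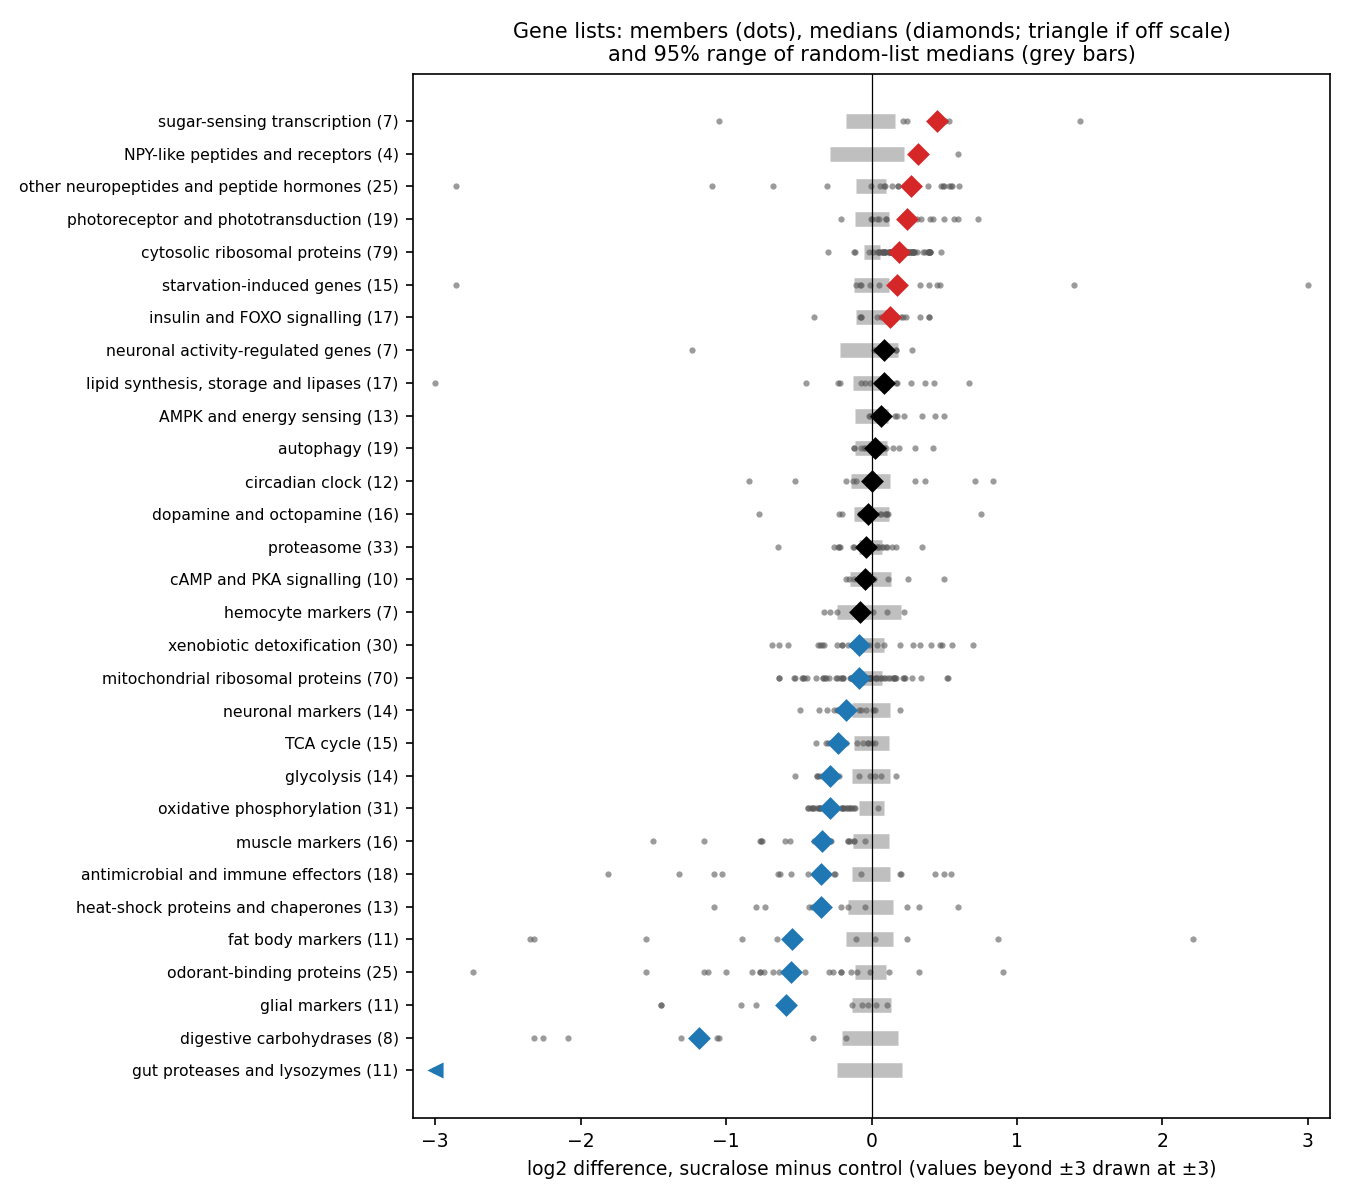
Log2 difference (sucralose minus control) of the members (dots) and medians (diamonds, or a triangle where off the scale) of 30 gene lists with the number of members over the floor in brackets, and grey bars for the central 95% of random-list medians, 1 library per diet. The medians run from -4.29 for gut proteases and lysozymes to 0.45 for sugar-sensing transcription.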

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

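Scaling without the 20 most abundant genes, counting without the tissue lists, random lists matched on length and lists without Akh were chosen after seeing the data. The number of genes beyond 1.5-fold or 2-fold depended on the pseudocount and the filter. With a pseudocount of 5, 61 genes were at least 1.5-fold higher and 206 lower, and 13 were at least 2-fold higher and 65 lower, since a larger pseudocount shrinks low genes. With no filter the counts were 459, 695, 83 and 210 over 12083 genes. With a floor of 200 reads they were 84 and 216 at 1.5-fold and 68 lower at 2-fold over 7341 genes. Lower genes outnumbered higher ones at both marks in each of these. The other alternatives kept each count within 1.5 times, and scaling moved the median of all genes by at most 0.0053. Without the gut, carbohydrase, muscle and fat body lists, 172 genes were at least 1.5-fold higher and 338 lower. Of the 21 lists called, 16 kept their call under every alternative run, and 5 lost it under some: detoxification, neuronal markers, other neuropeptides (mean), heat-shock genes (mean) and mitochondrial ribosomal proteins. With the mean, the AMPK list became higher (0.15) and the lipid list lower (-0.26). Direction was checked only for named genes at least 1.5-fold higher or lower, and 0 of their values turned. That outcome was fixed in advance and is no evidence of robustness. Pseudocounts and filters cannot change a gene's direction, and the scalings moved values far too little to turn a 1.5-fold difference. Of all 1116 values of named genes, 35 fell outside the gene's own counting interval. No paired analysis was possible because there is 1 library per diet. Depth limits genes such as the sweet taste receptors, which had 58 and 52 reads in all.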

Other observations

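Genes and lists in this part were chosen after their values were seen, except where stated. Genes of tyrosine breakdown were higher in the sucralose library. Of 7, Tat (1.80-fold, 1.72 to 1.89), Hpd (3.97-fold, 3.69 to 4.28) and hgo (2.03-fold, 1.73 to 2.39), which encode successive early enzymes of the pathway, were at least 1.5-fold higher, none was as much lower, and the median of 0.36 lay above 9998 of 10000 random lists. As Hpd was already among the named genes, this rank is not independent evidence. The 13 mRNAs encoded by mitochondrial DNA were all lower, 8 by at least 1.5-fold, with a median of -0.63 below all 10000 random lists, and they took 5.45% of control and 3.62% of sucralose reads. Among them mt:ND2 was 2.22-fold lower (2.06 to 2.41) and mt:CoI 1.37-fold lower (1.36 to 1.38).

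Of the identifiers with no matched symbol, FBgn0013984 was 2.16-fold higher (1.91 to 2.44) and FBgn0028420 1.75-fold higher (1.61 to 1.89). FBgn0261362 was 2.42-fold lower (1.83 to 3.22) and FBgn0010381 2.38-fold lower (1.77 to 3.24). The genes behind these identifiers were not determined. Whether the insulin receptor gene InR, which had no matched identifier, is among them was not tested.

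The tests of glia, retina, muscle and of reads taken by a few genes below were chosen or revised after their values were seen. For glia, bounds set beforehand (at most -0.5 for a loss of glia, at least -0.2 against it) left the median undecided, and counts of markers standing apart, added afterwards, did not settle it. For retina the bounds were set beforehand and the comparison with ninaE was added. For muscle, the verdict turned with the way markers were counted, so it is left open.

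Digestive enzyme genes were lower in the sucralose library by large folds. Midgut carried into the control heads may account for this, or lower expression of digestive enzymes alone on the sucralose diet. Midgut genes outside the proteases, listed before their values were seen, should separate these, but just 2 passed the floor, with a median log2 difference of -0.12, and the other 13 summed to 50 control and 31 sucralose reads. With so few reads, the explanations cannot be told apart for these genes. Akh was lower in the same library, and whether it shares a cause with them was not tested.

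Astrocyte genes such as Gat and alrm were lower and rhodopsin genes higher. Fewer glia overall would lower glial genes alike. Among 8 other glial genes the median was -0.21, below 9891 of 10000 random lists, with 3 at least 1.5-fold lower. Of 11 fixed markers, 5, among them repo (0.956, 0.854 to 1.07), had counting intervals above the list's median fold of 0.664. With 11 markers, 5 point values lie above the list's own median whatever the cause, but whole intervals need not. Counting error alone therefore does not account for the distance of those 5 from the median. The intervals leave out all other spread, and log2 differences of all genes had a robust SD of 0.222. Of those 5, 2 (CG6126 and wrapper) also cleared 0.903, a margin of 2 robust SDs, 1 short of the 3 required. The marker loco, with a lower limit of 0.902, fell just short of it. Fewer glia and a difference within astrocytes therefore cannot be told apart for these genes, on a margin this narrow and with no replicates. More retina would raise other photoreceptor genes by about as much as ninaE (0.56), but 12 of them had a median of 0.046 (SD 0.25). That argues against retina as the cause of a change of that size. A smaller gain may remain, as the fixed list of 19 photoreceptor genes, rhodopsin genes among them, had a median of 0.24. Rhodopsin transcripts and the diet itself stay untested.

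Of 31 oxidative phosphorylation genes, 30 were lower by small amounts that varied, from ND-MLRQ (fold 0.739) to ND-49 (0.923), and ND-51 was not (1.03, 0.988 to 1.07). Gene length bias is argued against, since 2 of 10000 random lists matched on length and expression had a median as low, and so is a few genes taking most of the reads, which would lower all other genes alike, since the median of all 8889 genes scaled by total counts was 0.0036. Less muscle in the sucralose heads stays open, since muscle markers had a median of -0.34, below that of oxidative phosphorylation. The counting intervals of 3 of 16 (bt at 0.967, Act57B at 0.921 and sls at 0.894) lay above the oxidative phosphorylation fold of 0.819. Those intervals cover counting error only, while log2 differences of all genes had a robust SD of 0.222. The 3 markers therefore do not settle whether all muscle was lost alike. A response to the diet may equally be involved and was not tested.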
